A study of Homo sapiens with 6 samples.

How the data were processed

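The labels' protocols name a total RNA extraction with Trizol from HT29 cells and an Illumina TruSeq RNA library kit, and 6 libraries were sequenced: 3 from cells that received a nonspecific control siRNA and 3 from cells that received an siRNA against RNF6. Groups and replicate numbers were taken from the sample titles. HT29 is an established human colorectal adenocarcinoma line. Poly-A selection, read length, the sequences of the siRNAs, the number of different siRNAs and the time between transfection and harvest are not given in the sources used here.

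The authors deposited 1 table of whole-number read counts per gene symbol for each library, not normalised. Per the submitters' processing notes, reads were aligned with TopHat2 2.0.11 and counted with HTSeq, and the genome build was hg19, also called GRCh37. The HTSeq version, its strand setting, the annotation release and any read filter are not given in the sources used here. Without a stated strand setting, reads from a gene and from an overlapping or antisense partner cannot be told apart. HTSeq sets aside reads that match several genes or several places, so a gene that shares sequence with a paralog or pseudogene loses reads, and its level is uncertain. The deposited tables list 56638 symbols, together with rows for reads without a feature, ambiguous reads and reads with several alignments. Those rows held between 27.3% and 29.4% of the listed reads of a library, and they were left out of library sizes and tests. Ambiguous reads alone made up 8.27% to 9.11%. Reads without a feature varied more, from 5.90% in control replicate 2 to 9.23% in RNF6 siRNA replicate 3.

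Counts were analysed as deposited in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with its default minimum count of 10 and minimum total count of 15, which left 14685 genes. Libraries were scaled by TMM factors between 0.985 and 1.02. A quasi-likelihood model with robust dispersion estimates and the group as its only term was fitted to all 6 libraries (glmQLFit and glmQLFTest, two-sided), and p-values were adjusted by the Benjamini-Hochberg method over all genes tested. A gene was called at an adjusted p below 0.05. Every adjusted p given for a gene comes from this test unless another tool is named. Log2 fold changes are RNF6 siRNA minus control siRNA, with a prior count of 0.125, and their standard error is the fold change divided by the square root of the F statistic. Normalised read counts are CPM values, scaled to the reads assigned to genes and by TMM, and are given as mean ± SD with n = 3 per group.

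Gene lists, 45 in number, were written before the data were examined. They cover JAK-STAT components and STAT3 targets, reported RNF6 substrates, other pathways, markers of other cell types and RNA classes that can follow RNA quality. Older and newer symbols of list members were matched to the symbols of the counts through reference tables of gene names and aliases. Lists with at least 5 tested members, 40 in all, were tested with camera from limma 3.58.1 with a preset inter-gene correlation of 0.01, two-sided, adjusted over the 40 lists. The same test with an estimated correlation and the directional fry test were run beside it. Member counts are given over all genes tested and adjusted over the list alone.

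Genes named in the text follow a rule written before the data were examined. RNF6, PTPN6, STAT3, JAK1 and JAK2 are always named. So are the 12 largest rises and the 12 largest falls among called protein-coding genes with a mean of at least 5 CPM and no overlap between the groups' libraries. From each list past the threshold, and from 8 lists named in advance whatever their result, up to 4 called members with the smallest adjusted p are named, and the most abundant member is named for each list of another cell type. Some genes that the rule selects are not reported here. Genes outside the rule are said to have been chosen after their values were seen.

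GENCODE release 29 annotates GRCh38, another build than that of the counts. It was used for gene type and transcript sequence, and no genomic coordinate is given. It matched 63.0% of all listed symbols and 92.2% of the genes tested. The 3′ untranslated regions (UTRs) of 12273 tested protein-coding genes, each at least 50 nt long, were searched for all 7-base words. Each of 16378 words found in enough genes was tested in a linear model of the log2 fold change on its presence, adjusted for UTR length and GC content, with Bonferroni adjustment (Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1). Genes are not independent replicates in this model. Classes of longer and shorter sites were formed after the leading words were known, and their medians have bootstrap intervals of 95% over genes. A gene without an annotated 3′ UTR counted as not searched.

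The gene test was checked on 5 simulated data sets that used the means, library sizes and dispersions of the 14685 genes, with 200 genes changed in each. It recovered 54.1% of genes changed by a fold of 1.5, 85.7% of those changed by a fold of 2 and 98.8% of those changed by a fold of 4, with no call in the wrong direction. Unchanged genes made up 7.48% of its calls. The Benjamini-Hochberg cutoff depends on the share of genes that change. These percentages therefore need not hold for the real comparison, where 4806 genes were called. Camera called the shifted list in 5 of 5 simulations at a fold of 1.5 with 30 members, and 0 of 195 unchanged lists. The simulated genes were drawn independently of each other. Among real lists past the threshold, the estimated correlation was 0.400 for glycolysis and hypoxia genes and 0.409 for proteasome subunits. The 0 of 195 therefore does not show how often correlated lists are called in error. The search for 7-base words recovered the planted word in 20 of 20 runs on 12273 genes, and found 0 words where none had been planted. The planted log2 shift was −0.3, larger than the slope of the leading real word (−0.249), so smaller shifts were not checked. Fold changes were shuffled among genes for these runs, which removes any link with UTR composition. The 0 words therefore cannot exclude such a link in the real data.

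Alternatives chosen before the data were examined were size factors by the median-of-ratios method, upper-quartile scaling, no filter on low counts, DESeq2 1.42.0, limma-voom, the replicate number as a block, a fold threshold of 1.5 (glmTreat), an adjusted p below 0.01, and leaving out each library in turn. Others were added after the data had been seen: the share of no-feature reads as a covariate, removal of each library's trend on transcript length and GC content (mgcv 1.9.3), and a test without genes that hold a leading 7-base word in the 3′ UTR. Figures were drawn with matplotlib 3.10.9. No sample was left out of the main analysis. A range of adjusted p covers every alternative run for that gene, the replicate number as a block included, whether or not the alternative is named beside it.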

Results

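Messenger RNA levels were measured by RNA sequencing in cells labelled HT29, the name of an established human colorectal cancer line, with 3 libraries after transfection of a nonspecific control siRNA and 3 after an siRNA against RNF6. RNF6 is a RING-type E3 ubiquitin ligase. Gene counts of the control libraries summed to 7173957, 9096826 and 9366532 reads for replicates 1, 2 and 3, and those of the RNF6 siRNA libraries to 11051552, 6808771 and 11071456. Of 56638 listed gene symbols, 14685 had enough reads to be tested. The groups separated on the first principal component, which carried 62.9% of the variance. The second, with 18.2%, set control replicate 1 at one end and control replicate 2 and RNF6 siRNA replicate 1 at the other. The common biological coefficient of variation was 10.5%. The labels do not say that the replicates were separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

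The comparison asks which transcripts change when RNF6 is depleted, and the series places it in the question of whether RNF6 activates JAK/STAT3 signalling through ubiquitylation of SHP-1, the phosphatase encoded by PTPN6. RNF6, on chromosome 13, was the target and fell in every RNF6 siRNA library. Its level was 54.3, 45.2 and 57.8 CPM in control replicates 1, 2 and 3, and 16.5, 16.2 and 16.9 CPM in the RNF6 siRNA replicates. The means were 52.5 ± 6.51 and 16.5 ± 0.316 CPM (SD, n = 3), a level 3.17-fold lower (log2 fold change −1.66, SE 0.126, adjusted p = 2.12e-06). STAT3, the transcription factor named by the series, rose 1.70-fold, from 125 ± 3.89 to 212.6 ± 7.15 CPM (adjusted p = 5.40e-05). PTPN6 was 1.30-fold lower, at 45.4 ± 6.68 CPM in control and 34.7 ± 3.12 CPM in RNF6 siRNA libraries (adjusted p = 0.0376). JAK2 was 1.38-fold lower, at 19.5 ± 4.38 and 14.1 ± 1.40 CPM (adjusted p = 0.0462). JAK1 had 202 ± 21.4 and 212.4 ± 16.3 CPM, a difference smaller than the spread between replicates (log2 fold change 0.07, SE 0.105, adjusted p = 0.633). Protein levels, ubiquitylation and phosphorylation were not measured here.

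The PTPN6 call ended without control replicate 2 (adjusted p = 0.0741), control replicate 3 (0.167), RNF6 siRNA replicate 2 (0.132) or RNF6 siRNA replicate 3 (0.0826), and over all alternatives its adjusted p ran from 0.00142 to 0.167. The JAK2 call ended without control replicate 1 (adjusted p = 0.1246), control replicate 3 (0.0950), or RNF6 siRNA replicate 1 (0.118), 2 (0.0718) or 3 (0.113), and also with upper-quartile scaling (0.0511), DESeq2 (0.0526) and limma-voom (0.0560). Its range over all alternatives was 1.48e-04 to 0.133.

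**Figure D1:**
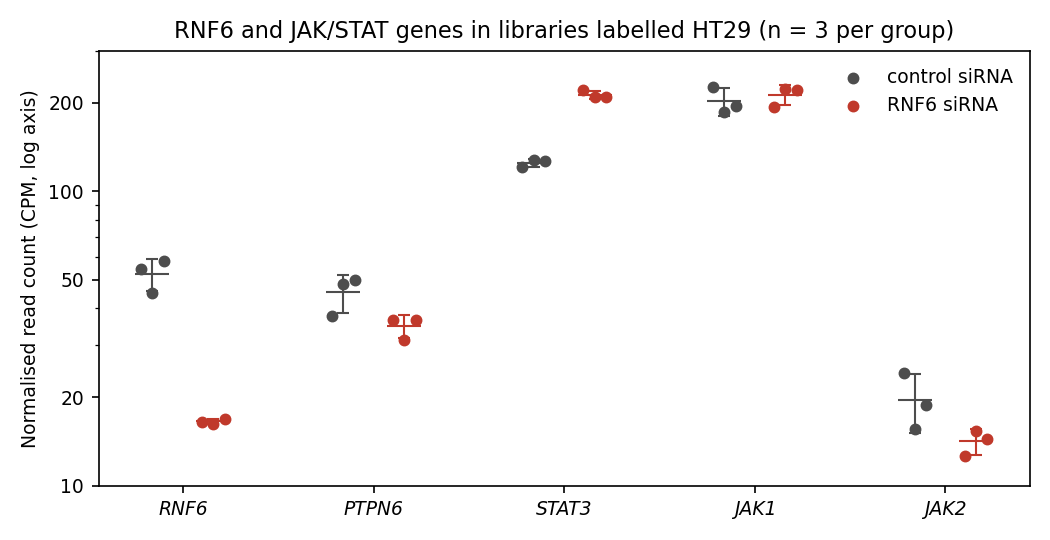
Normalised read counts (CPM, log axis) of RNF6, PTPN6, STAT3, JAK1 and JAK2 in each library, with control siRNA in grey, RNF6 siRNA in red, points for libraries, horizontal marks for means and bars for ± SD (n = 3). RNF6 lies at 16.2 to 16.9 CPM in the RNF6 siRNA libraries and at 45.2 to 57.8 CPM in the control libraries, STAT3 lies higher after RNF6 siRNA in all libraries, and JAK1 overlaps between the groups.

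Across the transcriptome, 2442 genes were higher and 2364 lower after RNF6 siRNA, together 32.7% of the genes tested. A fold of at least 2 was reached by 454 of the higher and 389 of the lower genes. The libraries of the groups did not overlap for 44.2% of tested genes, against 10% by chance in a design of 3 against 3. Without control replicate 3, 1514 genes were higher and 1595 lower, and without RNF6 siRNA replicate 3, 1529 were higher and 1478 lower.

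Among called protein-coding genes with a mean of at least 5 CPM and no overlap between the groups, the largest falls were led by CALB2, which encodes the calcium-binding protein calretinin. It fell 8.55-fold, from 14.5 ± 2.97 to 1.67 ± 0.172 CPM (log2 fold change −3.10, SE 0.217, adjusted p = 1.28e-06). LITAF fell 7.28-fold, from 127.2 ± 4.90 to 17.5 ± 0.907 CPM. MYD88, the adaptor of Toll-like and interleukin-1 receptors, fell 5.15-fold, from 28.2 ± 2.42 to 5.38 ± 0.859 CPM. CDC42 fell 4.61-fold, from 250.5 ± 5.59 to 54.5 ± 4.58 CPM. The rest of the 12 were RITA1 (4.66-fold), DOLK (4.51-fold), TNS4 (4.49-fold), the RNA export factor ALYREF (4.35-fold), the ribosomal protein gene RPL30 (4.30-fold), MRPL20 (4.19-fold), PLEKHA3 (4.16-fold) and the histone variant gene H2AFZ (4.14-fold). Each of these 12 had an adjusted p of 3.13e-06 or less, the value of DOLK. Annotated exons of other genes overlap 65.1% of CDC42, 39.3% of RPL30 and 27.6% of MRPL20, and the first 2 belong to families with near-identical pseudogenes, so their levels are uncertain. The pseudogene CDC42P6, chosen after its values were seen, fell 3.14-fold with its parent.

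Under the same criteria the largest rise was that of CYP1B1, a cytochrome P450 that oxidises steroids and aromatic hydrocarbons. It rose 4.59-fold, from 2.29 ± 0.279 to 10.6 ± 2.79 CPM (adjusted p = 3.87e-05). The kinase gene CDK14 rose 4.44-fold, from 5.39 ± 1.29 to 23.8 ± 1.49 CPM. GANAB, the catalytic subunit of endoplasmic reticulum glucosidase II, rose 4.27-fold, from 161.7 ± 6.85 to 690.5 ± 25.6 CPM, with an adjusted p of 6.35e-08. Others among the 12 largest rises were those of P4HA1 (4.31-fold), the glucose transporter gene SLC2A3 (3.75-fold), the methyltransferase gene SETD7 (3.68-fold), ZNF468 (3.50-fold), ARHGAP19 (3.43-fold), the p53-inducible antiproliferative gene BTG2 (3.32-fold), SRD5A1 (3.24-fold) and IGFBP3 (3.20-fold). Annotated exons of other genes overlap 56.8% of ZNF468 and 26.8% of ARHGAP19. The call of P4HA1 ended without control replicate 2 (adjusted p = 0.127), without RNF6 siRNA replicate 1 (0.0826) and without the filter on low counts (0.106), over a range of 1.17e-12 to 0.127. The call of SLC2A3 ended without control replicate 2 (adjusted p = 0.0782) and without the filter on low counts (0.0732), over a range of 2.92e-14 to 0.0782.

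Of 40 gene lists tested, 11 passed the threshold. When camera estimated the inter-gene correlation in place of the preset 0.01, 0 of the 40 passed and 5 had an unadjusted p below 0.05. The directional fry test, which does not compare a list with other genes, called 20 lists.

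Genes of glycolysis and the hypoxia response rose together. Of 30 tested members, 23 rose, 2 fell and 5 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 7.71e-08, and adjusted p = 0.390 with an estimated correlation). The median log2 fold change was 0.73. GPI, which isomerises glucose 6-phosphate, rose 2.09-fold, from 389.8 ± 53.2 to 814.5 ± 64.5 CPM. PFKL rose 1.96-fold, the neuronal enolase gene ENO2 2.08-fold and the aldolase gene ALDOA 1.79-fold, although 84.5% of ALDOA lies under annotated exons of other genes. The 2 members that fell, chosen after their values were seen, were the glucose transporter gene SLC2A1 (1.65-fold) and the triosephosphate isomerase gene TPI1 (1.27-fold). The TPI1 call ended without control replicate 3 (adjusted p = 0.0639), RNF6 siRNA replicate 2 (0.122) or RNF6 siRNA replicate 3 (0.104), over a range of 0.00302 to 0.122. Control replicate 1 stood apart in this group: P4HA1 was at 138.1 CPM there against 50.9 and 46.3 CPM in control replicates 2 and 3. Without control replicate 2, 10 of the members rose.

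Transcripts that report output of the MAPK pathway fell. Of 17 tested members, 10 fell, 0 rose and 7 did not pass, and 12 fell when adjusted over the list alone (camera adjusted p = 5.94e-07, and adjusted p = 0.206 with an estimated correlation). The estimated correlation of this list was 0.00975, not above the preset 0.01, so a higher correlation does not account for that change. The phosphatase gene DUSP6, a feedback inhibitor of ERK, fell 2.43-fold, from 497.8 ± 31.6 to 204.8 ± 26.9 CPM, with 39.4% of it under exons of other genes. DUSP4 fell 1.79-fold, SPRED2 1.82-fold and the cyclin D1 gene CCND1 1.81-fold, from 1059 ± 111.2 to 583.3 ± 27.0 CPM.

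Genes of G2 and mitosis rose: 20 of 38 tested members rose and 0 fell, with the same counts adjusted over the list alone (camera adjusted p = 2.83e-06, and adjusted p = 0.296 with an estimated correlation). CENPF, a kinetochore protein gene, rose 2.63-fold, from 156.2 ± 33.0 to 409.9 ± 43.9 CPM. UBE2C, the ubiquitin-conjugating enzyme of the anaphase-promoting complex, rose 1.75-fold and the cyclin gene CCNB2 1.76-fold. NUSAP1 rose 1.83-fold, with 72.8% of it under annotated exons of other genes. Without control replicate 3, 13 members rose, and without control replicate 2, 1 member fell. Genes of E2F and DNA replication did not move as a list, with 9 of 45 higher and 6 lower, the same counts adjusted over the list alone (camera adjusted p = 0.476). Within it, the cyclin E gene CCNE1 fell 2.47-fold and RPA2 1.47-fold, while the ribonucleotide reductase gene RRM1 rose 1.43-fold. Of 17 listed replication-dependent histone genes only 8 had enough reads to be tested, and HIST1H1B, HIST1H1D and HIST2H2AA3 had 0 reads. The result therefore covers part of the class. Transcripts of this list, one of the RNA classes that can follow RNA quality, rose for 5 of 8 tested members and fell for 0, with the same counts adjusted over the list alone (camera adjusted p = 0.00460, and adjusted p = 0.390 with an estimated correlation). These were HIST1H2BD (3.15-fold), HIST1H2AC (2.15-fold), HIST1H2BC (2.18-fold), HIST1H1C (1.46-fold) and, chosen after its values were seen, HIST1H2BK (1.28-fold), which share sequence with paralogs and are uncertain. The HIST1H1C call ended without control replicate 3 (adjusted p = 0.0810) or RNF6 siRNA replicate 2 (0.0666), over a range of 1.49e-04 to 0.0810, and 3 members of the list rose in either case. The HIST1H2BK call ended without control replicate 2 (adjusted p = 0.0658), control replicate 3 (0.0948), or RNF6 siRNA replicate 1 (0.0524), 2 (0.0879) or 3 (0.0722), without the filter on low counts (0.0779) and with DESeq2 (0.0546), over a range of 0.00964 to 0.113.

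Interferon-stimulated genes fell. Of 33 tested members, 17 fell, 0 rose and 16 did not pass, and 21 fell when adjusted over the list alone (camera adjusted p = 6.18e-05, and adjusted p = 0.296 with an estimated correlation). The antiviral gene OASL fell 2.45-fold, from 13.8 ± 2.78 to 5.65 ± 1.12 CPM, and the ubiquitin ligase gene DTX3L fell 2.39-fold. IFIT5 fell 1.71-fold and the transcription factor gene IRF1 1.54-fold.

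Of 28 tested STAT3 target genes, 12 fell, 5 rose and 11 did not pass, and 14 fell when adjusted over the list alone (camera adjusted p = 0.00481, and adjusted p = 0.390 with an estimated correlation). The cytokine receptor gene TNFRSF12A fell 2.78-fold, from 119.4 ± 17.0 to 42.9 ± 5.20 CPM. The anti-apoptotic gene MCL1 fell 2.04-fold, from 326.6 ± 23.9 to 160.1 ± 6.08 CPM. The chaperone gene HSPA4 fell 1.82-fold and CCND1 1.81-fold. The 5 that rose were STAT3 itself, BIRC5 (1.88-fold), and, chosen after their values were seen, AKT1 (1.68-fold), VEGFA (1.46-fold) and CDC25A (1.43-fold). For the JAK-STAT components, 12 of 37 were lower and 3 higher, and adjusted over the list alone 15 were lower and 4 higher (camera adjusted p = 0.0676). SOCS2, a feedback inhibitor of cytokine receptors, fell 2.51-fold and the receptor gene IL4R 2.02-fold, while PTPN11, which encodes the phosphatase SHP-2, rose 2.07-fold, from 171.1 ± 31.0 to 353.9 ± 27.0 CPM. The only other higher member, chosen after its values were seen, was IL6R (1.48-fold). Without control replicate 2 the list passed (adjusted p = 0.0191), as it did without RNF6 siRNA replicate 3 (0.0470). Without control replicate 1, 5 members were higher. Among 10 tested genes whose proteins have been reported as RNF6 substrates, LIMK1 (1.66-fold), TRIB3 (1.63-fold) and QSOX1 (1.21-fold) rose and PTPN6 fell, and adjusted over the list alone 2 fell (camera adjusted p = 0.804). The QSOX1 call ended without control replicate 2 (adjusted p = 0.0588), control replicate 3 (0.185), or RNF6 siRNA replicate 1 (0.0995), 2 (0.0886) or 3 (0.0668), without the filter on low counts (0.110) and with the trend on length and GC content removed (0.0807), over a range of 0.00189 to 0.185.

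Targets of p53 went both ways, more often up. Of 24 tested members, 12 rose, 4 fell and 8 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.00232, and adjusted p = 0.296 with an estimated correlation). The DNA repair genes XPC and DDB2 rose 2.15-fold and 1.98-fold, and BTG2 rose as given above. The cell-cycle inhibitor gene CDKN1A fell 2.29-fold, from 876.1 ± 61.2 to 382.4 ± 39.2 CPM. The other 3 that fell, chosen after their values were seen, were PLK3 (1.35-fold), GDF15 (1.31-fold) and C12orf5 (1.27-fold), the last with 45.3% under exons of other genes. The PLK3 call ended without RNF6 siRNA replicate 2 (adjusted p = 0.0595) or 3 (0.0793), over a range of 6.42e-04 to 0.0793. The GDF15 call ended without control replicate 2 (adjusted p = 0.0531) or 3 (0.0644) and without RNF6 siRNA replicate 2 (0.104) or 3 (0.107), over a range of 1.99e-04 to 0.107. The C12orf5 call ended without the same 4 libraries in turn (adjusted p = 0.0649, 0.190, 0.0730 and 0.193), with upper-quartile scaling (0.0563) and with DESeq2 (0.0527), over a range of 0.00639 to 0.193. Of the list's members, 2 were lower without control replicate 2 or 3, and 1 without RNF6 siRNA replicate 2 or 3. Among 24 pro-apoptotic genes, 6 rose and 2 fell, and 4 fell adjusted over the list alone (camera adjusted p = 0.549). The BH3-only gene BBC3 rose 2.18-fold, the death receptor gene TNFRSF10B rose 1.27-fold, and BID (1.43-fold) and, chosen after its values were seen, CASP9 (1.42-fold) fell. The TNFRSF10B call ended without control replicate 3 (adjusted p = 0.0571, over a range of 5.74e-05 to 0.0649), where 3 members of the list rose. The CASP9 call ended without RNF6 siRNA replicate 3 (adjusted p = 0.0548, over a range of 0.00277 to 0.0554). In this list 5 members fell without control replicate 1, and 1 without RNF6 siRNA replicate 3. Of 12 anti-apoptotic genes, BCL2L2 (1.85-fold) and BIRC5 rose, and MCL1, BAG3 (1.67-fold) and, chosen after its values were seen, BIRC3 (1.59-fold) fell, with the same counts adjusted over the list alone (camera adjusted p = 0.978). The BIRC3 call ended without RNF6 siRNA replicate 3 (adjusted p = 0.0677, over a range of 5.65e-05 to 0.0677). Without control replicate 1, 4 anti-apoptotic genes rose.

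Genes of cholesterol synthesis fell for 12 of 24 tested members, with 1 that rose, and 13 fell adjusted over the list alone (camera adjusted p = 8.04e-04, and adjusted p = 0.296 with an estimated correlation). NSDHL fell 2.34-fold, the lanosterol synthase gene LSS 1.85-fold and SREBF2, the transcription factor gene of the pathway, 1.602-fold, from 192.6 ± 10.5 to 120.2 ± 8.01 CPM. INSIG1, chosen after its values were seen, was the member that rose (1.37-fold). Its call ended without control replicate 2 (adjusted p = 0.0684), control replicate 3 (0.119) or RNF6 siRNA replicate 2 (0.0974), over a range of 2.15e-04 to 0.119. Without control replicate 1, 2 genes of the list rose.

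Among 33 proteasome subunits, 16 fell and 1 rose, the same counts adjusted over the list alone (camera adjusted p = 0.00173, and adjusted p = 0.686 with an estimated correlation). PSMD14 fell 1.67-fold, PSMD8 1.66-fold and PSMD13 1.57-fold, while PSMC3 rose 1.61-fold. Without control replicate 3 or RNF6 siRNA replicate 3 the number that fell was 10, and without RNF6 siRNA replicate 2 it was 9. Of 29 genes of ribosome biogenesis and MYC targets, 13 fell and 1 rose, and adjusted over the list alone 14 fell and 3 rose (camera adjusted p = 0.00460, and adjusted p = 0.390 with an estimated correlation). GNL3 fell 1.52-fold, WDR43 1.54-fold, the polyamine enzyme gene ODC1 1.47-fold and WDR12 1.47-fold. The member that rose, chosen after its values were seen, was the lactate dehydrogenase gene LDHA (1.33-fold), which also belongs to the glycolysis list. The LDHA call ended without control replicate 2 (adjusted p = 0.0708), control replicate 3 (0.232), RNF6 siRNA replicate 2 (0.189) or RNF6 siRNA replicate 3 (0.0619), and with the share of no-feature reads as a covariate (0.275), over a range of 9.67e-05 to 0.275. Of 19 heat shock and chaperone genes, 9 fell and 2 rose, and 10 fell adjusted over the list alone (camera adjusted p = 0.0219, and adjusted p = 0.390 with an estimated correlation). HSF1, the master transcription factor gene of the heat shock response, fell 2.24-fold, HSPH1 fell 1.78-fold and HSPA4 fell as given above. The mitochondrial chaperonin gene HSPD1 rose 1.61-fold. The other riser, HSF2 (1.28-fold), was chosen after its values were seen, and its call ended without control replicate 3 (adjusted p = 0.136), RNF6 siRNA replicate 2 (0.0935) or RNF6 siRNA replicate 3 (0.0572), over a range of 4.36e-04 to 0.136. Without RNF6 siRNA replicate 2 the number of chaperone genes that fell was 4, and without RNF6 siRNA replicate 3 it was 5.

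**Figure D2:**
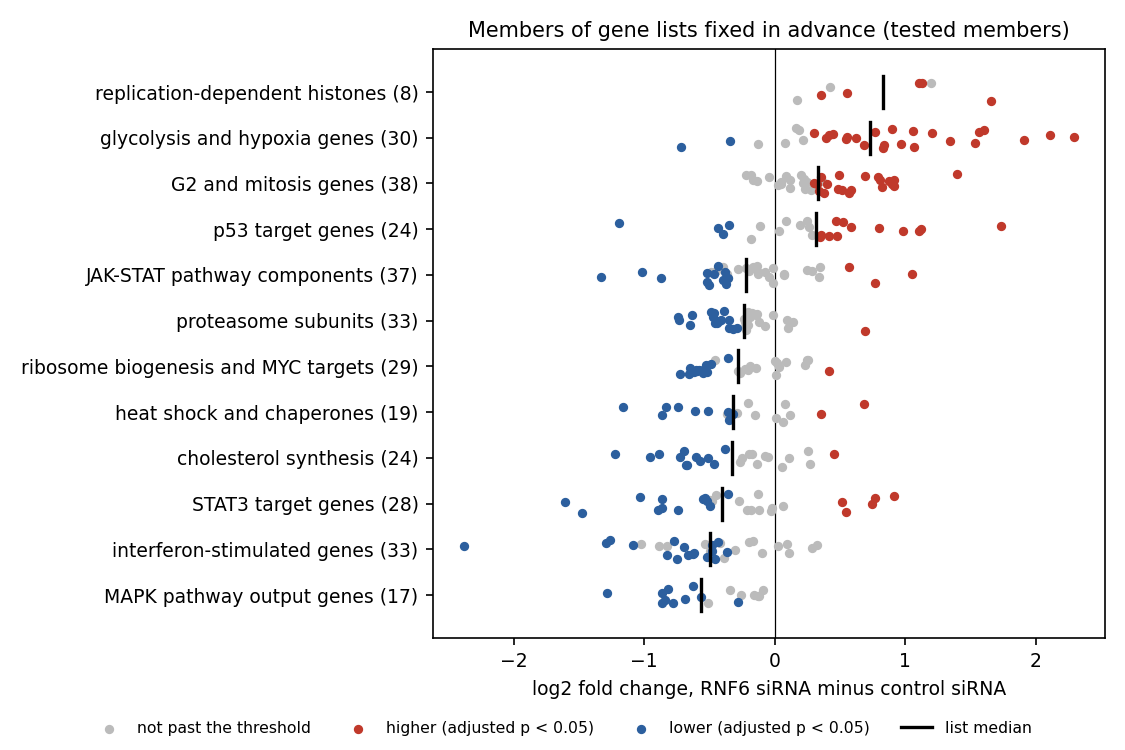
Log2 fold change (RNF6 siRNA minus control siRNA) of every tested member of the 11 gene lists past the threshold and of the JAK-STAT components, which did not pass (camera adjusted p = 0.0676), with a point per gene (red higher, blue lower, grey not called), a black bar at each list's median and the number of tested members after its name. Glycolysis and hypoxia genes have a median of 0.73, and the MAPK output genes have a median of −0.57 with 10 lower and 0 higher.

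Genes that carried certain short sequences in the 3′ UTR differed from genes that did not, a search described before its result was seen, except for its site classes. Of 16378 words of 7 bases, 18 with a negative and 9 with a positive slope passed the Bonferroni threshold. The word ACAGACA had the most negative slope of all (t = −18.32, Bonferroni-adjusted p = 9.08e-70). Of 1689 genes that held it, 29.5% were lower, against 16.1% of genes that did not. The median log2 fold change was −0.20 for the 484 genes with TACAGACA, and 0.01 for the 8694 genes with no site. The 8-base word occurs once in each of 3 annotated RNF6 transcripts, in the coding sequence, at positions 669 to 676 of RNF6-201, 798 to 805 of RNF6-202 and 1099 to 1106 of RNF6-203 (GENCODE 29, counted from the first base of the transcript). Among the 12 largest falls, 8 genes held the 8-base word or a 7-base part of it: CALB2, LITAF, MYD88 and H2AFZ the longer, and RITA1, DOLK, MRPL20 and PLEKHA3 a shorter. Of other genes that fell and are named above, MCL1, HSPA4 and SLC2A1 held TACAGACA, and TNFRSF12A, DTX3L, IRF1, NSDHL, LSS, SREBF2, PSMD13, HSF1, C12orf5 and CASP9 held a 7-base part, as did SPARC and ALPL among the markers given below. Named genes that rose and held a 7-base part were SRD5A1, PTPN11, QSOX1, HIST1H2BD and, among the markers, COL1A1. No such site was annotated for RNF6, JAK2, CDC42, RPL30, CDKN1A, DUSP6 or CCND1, and PTPN6 held the central 6 bases only. On the rising side the leading word was CGGAGAA (t = 7.81), where 35.6% of 275 genes were higher, against 16.0% of those without it. Of the 12 largest rises, 9 held CGGAGAAA or a 7-base part of it, against 21.7% of all genes searched, and for the falling word the share of all genes searched was 17.5%. All of these 9 but CDK14 held only the part GGAGAAA, a common word with a small slope (log2 0.0893). It occurred in 2558 genes, of which 23.5% were higher, against 14.6% of those without it. TCGGAGA, which also overlaps CGGAGAA, had a slope of 0.235 in 239 genes, against 0.234 for CGGAGAA. It was not used for the site classes. CDK14 held CGGAGAAA, as did the marker FBN1, given below. GANAB, SLC2A3, SETD7, ZNF468, ARHGAP19, BTG2 and IGFBP3 held the part GGAGAAA, as did STAT3, PTPN11, CENPF, XPC, HSPD1, TRIB3, QSOX1, BCL2L2 and IL6R among other named genes that rose, and HIST1H2BD held CGGAGAA. Of named genes that fell, CDC42, IFIT5, DUSP6, SREBF2, WDR12, HSPH1 and C12orf5 also held GGAGAAA, and PLEKHA3 and the marker DPP4 held CGGAGAA.

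**Figure D3:**
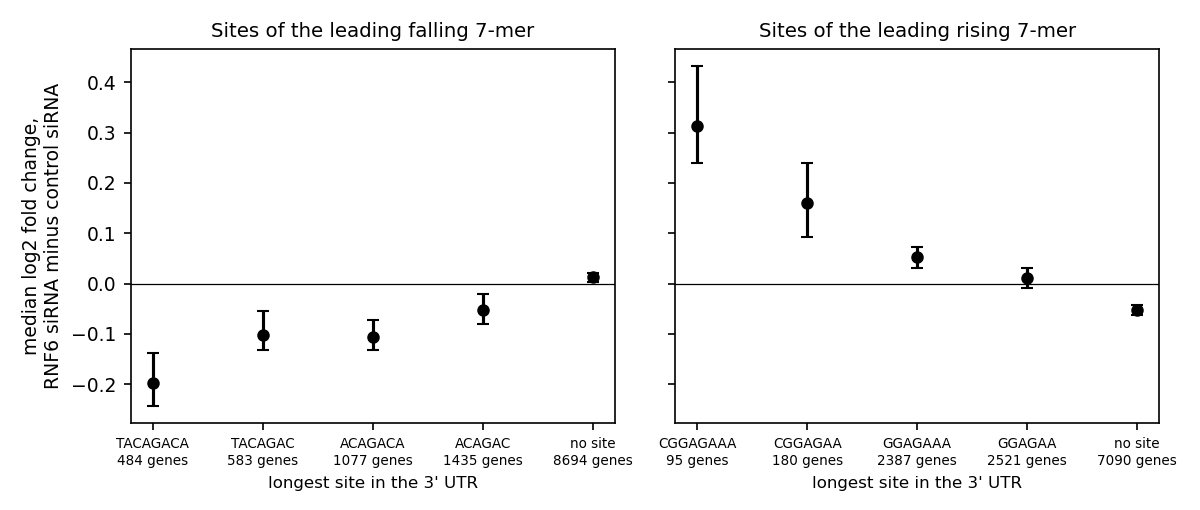
Median log2 fold change (RNF6 siRNA minus control siRNA) of genes grouped by the longest site in the annotated 3′ UTR, for the leading falling word (left) and the leading rising word (right), with bars for 95% bootstrap intervals over genes, which are not independent replicates. Genes with TACAGACA have a median of −0.20 and genes with CGGAGAAA a median of 0.31.

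When all genes with an 8-base or 7-base site of either kind were left out, an alternative added after the data had been seen, 4 of the 11 lists no longer passed. The mean log2 fold change of the cholesterol genes went from −0.35 (SD 0.423) to −0.17 (SD 0.362) over the 16 members left (adjusted p = 0.139). STAT3 targets went from −0.31 (SD 0.624) to −0.27 (SD 0.655) over 17 members (adjusted p = 0.0684), the heat shock genes from −0.29 (SD 0.451) to −0.22 (SD 0.299) over 15 (adjusted p = 0.114), and p53 targets from 0.31 (SD 0.608) to 0.26 (SD 0.611) over 14 (adjusted p = 0.0502). In this setting 4 lists passed that otherwise did not. Immediate early genes had a mean of −0.45 (SD 0.580) over 13 members (adjusted p = 4.73e-04), epithelial junction genes −0.38 (SD 0.661) over 16 (0.00840), JAK-STAT components −0.27 (SD 0.377) over 21 (0.0102), and NF-κB and inflammatory genes −0.40 (SD 0.551) over 14 (0.0142). The words were chosen by their link with these same fold changes, so leaving out their carriers can by itself shift a list either way. Of 25 immediate early genes searched, 13 held a rising site, among them 3 of the 4 that rose, and 1 held a falling site. The lists lost and gained in this setting therefore cannot show which list changes stand apart from the sites.

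The other lists did not pass over all genes tested, with camera adjusted p between 0.0676 and 0.984. Of 18 NF-κB and inflammatory genes, 7 were lower and 1 higher. The counts were 13 lower and 4 higher of 26 immediate early genes, 8 lower and 4 higher of 18 Hippo and YAP targets, 4 lower and 0 higher of 9 enterocyte genes, and 6 lower and 4 higher of 29 genes of autophagy and lysosomes. Epithelial junction genes had 8 lower and 4 higher of 26, TGF-β and matrix genes 9 lower and 7 higher of 25, mesenchymal transition genes 5 lower and 3 higher of 14, and Wnt targets and stem cell genes 5 lower and 3 higher of 18. Among metabolic and stress lists, 4 of 26 ATF4 targets were lower and 8 higher, 2 of 20 unfolded protein response genes were lower and 2 higher, 5 of 24 NRF2 genes were lower and 7 higher, 3 of 15 fatty acid synthesis genes were lower and 5 higher, 4 of 35 oxidative phosphorylation genes were lower and 3 higher, and 0 of 5 metallothionein genes were lower and 2 higher. Of 15 CDK inhibitors and D-type cyclins, 3 were lower and 4 higher, and of 51 cytosolic ribosomal protein genes, 2 were lower and 3 higher. Of 15 antigen processing genes, 2 were lower and 2 higher, of 13 RNA interference genes, 2 were lower and 1 higher, and of 11 RING ligases related to RNF6, 2 were lower and 3 higher. Adjusted over the list alone, the counts were the same in 17 of the 29 lists that did not pass and differed by at most 3 in the other 12. Leaving out 1 library moved a member count by over 1.5 times in 22 of the 29. The NF-κB list passed without RNF6 siRNA replicate 1 (adjusted p = 0.0337), the immediate early list without RNF6 siRNA replicate 1 (0.0254), and the Hippo list without control replicate 2 (0.0480) or RNF6 siRNA replicate 3 (0.0470). Median, mean and test differed in sign for pro-apoptotic genes (median −0.09, mean 0.06), reported RNF6 substrates (median −0.16, mean 0.04), fatty acid synthesis genes (median −0.11, mean 0.02), CDK inhibitors (median 0.16, mean 0.03, test downward), NRF2 genes (median −0.03, mean −0.01, test upward), cytosolic ribosomal proteins (median 0.01, mean −0.05) and mitochondrial transcripts (median 0.01, mean −0.02).

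Markers of other cell types and of RNA quality were examined in the same way, and members named here besides the most abundant one of each cell type were chosen after their values were seen. Mitochondrial genome transcripts showed 0 called genes of 13. Of 14 housekeeping genes, 5 were higher (ACTB, GAPDH, GUSB, PGK1 and SDHA, by 1.23-fold to 1.37-fold) and 0 lower. Without control replicate 3 or RNF6 siRNA replicate 3, 0 of these genes were higher, against 1 without RNF6 siRNA replicate 1 and 3 without RNF6 siRNA replicate 2. Of 9 nuclear retained RNAs, KCNQ1OT1 (1.81-fold) and RN7SK (1.88-fold) were higher and MALAT1 (1.34-fold) lower. The RN7SK call ended without RNF6 siRNA replicate 1 (adjusted p = 0.134) or 3 (0.0968), over a range of 4.41e-04 to 0.134, and the MALAT1 call ended without RNF6 siRNA replicate 3 (0.0945), over a range of 0.00171 to 0.0945. The KCNQ1OT1 call ended with the trend on length and GC content removed (adjusted p = 0.0685).

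The most abundant lymphocyte marker, CORO1A, had 14.9 ± 5.68 and 21.6 ± 3.06 CPM in control and RNF6 siRNA libraries (adjusted p = 0.0779), and of 5 tested lymphocyte markers only CD79B was called, 3.20-fold lower at 3.43 ± 1.30 and 1.11 ± 0.271 CPM. CSF1R, the only tested myeloid marker, was 2.038-fold lower at 2.501 ± 0.551 and 1.25 ± 0.465 CPM. Of 4 stromal markers, COL1A1 was 1.33-fold higher at 56.7 ± 7.13 and 75.5 ± 7.45 CPM, FBN1 was 2.34-fold higher at 4.09 ± 0.629 and 9.72 ± 1.06 CPM, and SPARC was 2.44-fold lower at 8.01 ± 0.0847 and 3.23 ± 0.490 CPM. Of 3 endothelial markers, ESAM was 1.51-fold lower at 17.7 ± 3.05 and 11.7 ± 1.96 CPM, and VWF was 2.02-fold lower at 1.96 ± 0.391 and 0.9997 ± 0.187 CPM. SERPINA1, the only tested marker of liver and squamous lines, had 7.32 ± 1.16 and 5.93 ± 0.712 CPM and was not called. The calls of CSF1R, COL1A1, ESAM and VWF each ended without RNF6 siRNA replicate 3 (adjusted p = 0.162, 0.0727, 0.0850 and 0.122). CSF1R also lost its call without control replicate 3 (0.147) or RNF6 siRNA replicate 2 (0.0583) and with DESeq2 (0.0735). COL1A1 also lost it without control replicate 3 (0.0793) or RNF6 siRNA replicate 1 (0.0690), and ESAM without RNF6 siRNA replicate 2 (0.0603). VWF also lost it without control replicate 2 (0.0782) or 3 (0.119) or RNF6 siRNA replicate 1 (0.0630), with DESeq2 (0.109) and with the share of no-feature reads as a covariate (0.0838). Over all alternatives the adjusted p of CSF1R ran from 0.0149 to 0.162, of COL1A1 from 1.93e-05 to 0.0969, of ESAM from 8.66e-04 to 0.0850 and of VWF from 0.00890 to 0.122.

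Markers of differentiated colon were at or near 0 in both groups: 20 of 29 enterocyte genes and 18 of 21 goblet and secretory genes had too few reads to be tested. Of the tested enterocyte genes, 4 were lower, all chosen here after their values were seen. The carbonic anhydrase gene CA2 fell 3.23-fold, from 66.8 ± 5.76 to 20.8 ± 1.98 CPM. The peptidase gene DPP4 fell 1.44-fold, from 18.1 ± 2.25 to 12.4 ± 1.04 CPM, and its call ended without RNF6 siRNA replicate 3 (adjusted p = 0.0591, over a range of 0.00151 to 0.0591). KRT20 and ALPL, at 1.99 ± 0.534 and 2.997 ± 1.05 CPM in control libraries, were 3.04-fold and 2.05-fold lower. The ALPL call ended without control replicate 2 (adjusted p = 0.0641) or 3 (0.158) or RNF6 siRNA replicate 2 (0.101) or 3 (0.170), with DESeq2 (0.0568) and with the share of no-feature reads as a covariate (0.153), over a range of 0.00201 to 0.170. Without RNF6 siRNA replicate 3, 2 enterocyte genes were lower. Of 3 tested goblet genes only FCGBP, a component of mucus, was called, 2.03-fold higher at 3.07 ± 0.330 and 6.10 ± 1.07 CPM.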

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

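The covariate for no-feature reads, the correction for length and GC content and the test without genes that hold a 3′ UTR site were chosen after the data had been seen. The RNF6 log2 fold change lay between −1.60 and −1.77 over all alternatives run, and no called gene changed sign under any alternative. The numbers of genes higher after RNF6 siRNA and genes lower after RNF6 siRNA were within 1.5 times those reported (2442 and 2364) with RLE size factors, upper-quartile scaling, no filter on low counts, DESeq2, limma-voom, the no-feature covariate and the correction for length and GC content. The no-feature covariate raised the genes called from 4806 to 6236, and the correction for length and GC content called 6633 of 13542 annotated genes. With stricter thresholds, where fewer calls follow by construction, 312 genes were higher and 348 lower against a fold of 1.5, and 1382 were higher and 1367 lower at an adjusted p under 0.01. Without genes that hold a 3′ UTR site, where fewer genes were tested, 1502 were lower. Leaving out 1 library gave 1514 to 2910 higher and 1478 to 2967 lower genes, and 11 to 13 lists past the threshold. No list of the 11 passed when camera estimated the correlation (0 of 40, with 5 at an unadjusted p under 0.05), and fry called 20. The estimated correlation was not above the preset 0.01 for MAPK output genes (0.00975) or JAK-STAT components (0.00748). Their unadjusted camera p still went from 2.97e-08 to 0.00514 and from 0.0214 to 0.0759. For these lists a higher correlation is argued against as the reason, and the cause of the difference was not tested. With the replicate number as a block 1421 genes were higher and 1321 lower, and 57.0% of calls stayed. The block also ended the calls of 25 of the 133 genes examined singly, and for 5 genes its adjusted p is the upper end of the range given in the report: JAK2 (0.133), TNFRSF10B (0.0649), COL1A1 (0.0969), CASP9 (0.0554) and HIST1H2BK (0.113). No pairing by replicate number was seen. Libraries of equal number had correlations of −0.67, −0.44 and 0.10 between their deviations from the group means across genes, and control replicate 2 went most with RNF6 siRNA replicate 1 (0.69). Deviations within a group are tied to each other, and those of control replicates 1 and 2 were opposed (−0.86). A smaller effect of pairing therefore cannot be excluded. Gene counts of 6808771 to 11071456 reads per library limit what can be said of genes with few reads. In simulated data 54.1% of genes changed by a fold of 1.5 were called. With 200 of 14685 genes changed there and 4806 called here, that share need not hold for this comparison.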

Other observations

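The genes of the first 2 paragraphs, the classes of 3′ UTR sites, the correction for length and GC content, and the test of the line with its gene set and criterion were chosen only after the data had been seen. KRT8, an intermediate filament gene of glandular epithelium, fell 2.44-fold, from 3064.3 ± 441.9 to 1255.8 ± 103.8 CPM. Its filament partner KRT18 fell 3.07-fold, from 352.01 ± 62.6 to 114.8 ± 11.9 CPM, and KRT19 fell 1.51-fold. Both KRT8 and KRT18 have many pseudogenes of near-identical sequence, so their levels are uncertain. ITGA2, the α2 chain of a collagen receptor, fell 3.07-fold, from 330.2 ± 73.9 to 107.7 ± 16.8 CPM, and its annotated 3′ UTR holds TACAGACA. COL5A1 rose 4.06-fold from a low level, 0.743 ± 0.242 to 3.06 ± 0.0896 CPM.

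The transcription factor gene MYC fell 1.85-fold, from 221.3 ± 18.7 to 119.3 ± 15.7 CPM. The matricellular protein gene CTGF fell 2.41-fold, from 20.9 ± 1.41 to 8.68 ± 1.52 CPM, and the phosphatase gene DUSP5 fell 1.76-fold, from 392.4 ± 28.9 to 222.8 ± 26.0 CPM. The adhesion molecule gene ICAM1 fell 3.04-fold, from 6.42 ± 0.525 to 2.12 ± 0.522 CPM.

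Genes with ACAGACA in the 3′ UTR were lower after RNF6 siRNA (t = −18.32), by a factor of 2.67 ahead of the next falling word that shares no 6 bases with it. Seed-matched repression of other transcripts by the RNF6 siRNA, whose sequence is not given in the sources used here, is a hypothesis that this lead fits; the word occurs in 3 of 3 annotated RNF6 transcripts, but so do several of the leading rising words, so that match is not particular to it. As the direct cause of most falls it is argued against, since the excess of fallen genes that carry the word was 10.3% of the 2198 fallen genes searched (95% bootstrap interval 8.43% to 12.1%). This excess counts ACAGACA alone, over a rate in genes that may hold other sites of its family. Any 8-base or 7-base site of the family was held by 625 of these fallen genes, against 17.5% of all genes searched. Repression by the control siRNA, which would make its targets look higher after RNF6 siRNA, may add to the rises but is not decided, because the leading rising word, CGGAGAA, had 1.49 times the t of the next, just under the limit of 1.5 set before the result was seen. Effects of RNF6 loss, and effects that follow from repressed regulators, stay open for each gene, since 1 knockdown group was compared with 1 control group.

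The number of called genes, 4806, was set against the 9 other ways to split the 6 libraries into 3 and 3. Only 1 of the 10 splits, the real one, gave as many calls with edgeR, and the highest of the others gave 0, with 31 to 1986 genes at an unadjusted p under 0.05. With 10 splits no share under 0.05 can be reached. Every other split also mixes libraries of both siRNAs, which moves the difference between them into the spread within groups. Few calls there follow from the design, so 4806 against 0 decides nothing about the cause. A bias of transcript length or GC content as the whole cause is argued against, because 98.9% of the 4538 called genes with annotation stayed called in the same direction after each library's trend was removed. The corrected test called 6633 of 13542 annotated genes, more than before, so the high share kept follows in part from the added calls. The trends therefore bear on how many genes are called. Before that correction the log2 fold change had a Spearman correlation across genes of 0.13 with length and −0.05 with GC content, where genes are not independent replicates.

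Markers of differentiated colon were near the floor in all 6 libraries. Over 50 enterocyte and goblet genes the median of the highest CPM in any library was 0.304, and 30 of them had at most 5 reads in each library. CEACAM5 and LGALS4 had at most 2 reads, AGR2 at most 4 and VIL1 at most 5, and CEACAM6, TFF3 and CDX1 had 0 in all libraries. Only CDX2 (17.8 CPM at most), CA2 (69.9), DPP4 (20.9), FCGBP (6.77) and HNF4A (5.33) reached 5 CPM, which does not separate lines, since that level was chosen after the values were seen and other colorectal lines could reach it too. Cells of another line than the label names and an undifferentiated culture of HT29 both stay open and cannot be told apart here, where no reference profile of the line was used.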
